A study of Homo sapiens with 10 samples.

How the data were processed

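RNA of human endometrial stromal cells was measured on 10 Affymetrix arrays with 22277 probe sets each. The labels give 5 arms with 2 arrays each, numbered sample 1 and sample 2. The arms are a control siRNA (siCtrl), an siRNA against the progesterone receptor gene PGR (siPGR), and siPGR followed by adenovirus carrying flag-tagged PRA, flag-tagged PRB or both. Per the labels, the siRNA acted for 48 h, the adenovirus was given for 24 h and the differentiation cocktail for 6 h. The labels do not say whether the siCtrl and siPGR arms received a control virus, or whether samples 1 and 2 came from separate donors.

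The deposited table holds log2 probe set signals. Values ran from 2.25 to 14.69, and the medians of the arrays from 6.41 to 6.46. The authors name MAS5, Affymetrix Expression Console 1 and robust multi-array averaging (RMA) as processing tools, without their order or role, so the tool that made the table is not known. The values were used as deposited. No counts stand behind array signals, so the number of arrays limits the precision.

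Probe sets were assigned to genes by the platform annotation, and 19070 probe sets had a single gene symbol. A gene was represented by its probe set with the highest mean over the 10 arrays, which gave 11963 genes. A gene was tested if that probe set lay above the 40th percentile of the array on at least 2 arrays, which left 8243 genes. Probe sets with several symbols (1043) or none listed (2108) and the 62 control probe sets were left out of the gene tests. Positions are from the RefSeq annotation of GRCh38.

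Group means over all 10 arrays were fitted with limma 3.58.1 in R 4.3.3, with the empirical Bayes trend and robust options off. Tests were two-sided, and p was adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The 8 comparisons fixed before the data were examined were siPGR against siCtrl, PRA, PRB and both isoforms against siPGR, PRB against PRA, both isoforms against PRA and against PRB, and the departure of both isoforms from the sum of the single-isoform changes. The pooled comparisons of the 4 arrays with PRB against the 4 siPGR and PRA arrays, and of the 4 arrays with PRA against the 4 siPGR and PRB arrays, were added after the data had been seen. So was the test of whether the PRB change differed between the cell samples.

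The sample numbers name the cell sample each array came from. As a check of that pairing, deviations from the group mean were correlated between arms across genes, and the correlations ran from 0.37 to 0.89, so the numbers pair the arrays. A fit with the sample number as a block is given beside each result whose call it changed or whose count it moved by more than 1.5 times.

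The 27 gene lists fixed before the data were examined cover decidualization markers, genes responsive to progesterone and glucocorticoid receptors, to estrogen and to cAMP, immediate early genes, interferon response, inflammatory cytokines, S phase, G2 and M phase, extracellular matrix, matrix proteases, TGF-beta and BMP signalling, Wnt signalling, growth factors, cholesterol synthesis, the unfolded protein response, p53 targets, hypoxia and glycolysis, steroid receptors, metallothioneins, epithelial, endothelial, leukocyte, smooth muscle and stromal cell markers, heat shock and histone genes. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists within a comparison, with the estimated correlation and with fry beside it. Camera compares a list with the other genes. Fry tests whether a list's genes move on balance in either direction, without comparing them with other genes. List scores, the means of the members on each array, were also compared by two-sided exact permutation over the 35 splits of the 8 arrays other than siCtrl.

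The genes named were chosen by a rule fixed before the data were examined. For 5 of the comparisons it takes the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose difference has the same sign in both cell samples, and for both isoforms against PRA, both against PRB and the departure from the sum it takes 5 each way. A direction with fewer is filled from genes past the threshold with the block, and one that still has fewer than 5 gets the 5 genes with the largest value of the smaller of the 2 cell sample differences, as values. The rule adds up to 4 called members of each list, PGR, and 12 decidualization genes. Of these 12, PRL, WNT4, FKBP5 and ZBTB16 lay below the filter and HOXA10 had no probe set with a single symbol. The same rule was applied to the pooled comparisons.

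Alternatives were quantile normalization, median centring, no filter, a 60th percentile filter, the mean of a gene's probe sets, the trend and robust options, array weights, an added 1.5-fold threshold, only the arms compared, and leaving out each array in turn, with and without the block. An offset on the log scale was planned for linear values and did not apply. On data simulated with the gene means, the cell sample differences and the spread of the 10 arrays in the fit with the block, the fit without the block recovered 52.6% of genes changed by a log2 value of 1 between PRB and siPGR and 87.2% of those changed by 2, and the fit with the block 87.8% and 99% (500 simulated genes at each size, with 0.7 and 11.2 false calls per simulation). The simulated changes were equal in both cell samples and fell on randomly chosen genes. These shares therefore do not hold for changes that differ between the cell samples, and a lack of calls is not evidence of no change. RNA quality was read from the 3 prime minus 5 prime log2 signal of the GAPDH and ACTB control probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.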

Results

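The data were 10 expression arrays of human endometrial stromal cells, the fibroblast-like cells of the uterine lining that differentiate into decidual cells. The design asked which genes the isoforms PRA and PRB of the progesterone receptor regulate in differentiating cells, by silencing endogenous PGR with siRNA and returning PRA, PRB or both by adenovirus. PRA lacks the amino-terminal end of the longer PRB. Each of the 5 arms had 2 arrays, from cell samples 1 and 2. All values are log2 signals, differences are given with the standard error (SE) of the limma fit, and n = 2 arrays per arm unless stated. Outside the pooled comparisons the SE are from the fit without the block, so they include the difference between the cell samples. For PRB against siPGR the median SE over the genes was 0.18, and 0.13 with the block. Array signals carry no depth, so their number limits the precision. Median signals per array lay between 6.41 and 6.46. GAPDH 3 prime minus 5 prime signals were 0.51 on the PRB array of sample 2 and between 0.04 and 0.31 on the others, and those of ACTB were 1.34 and between 0.59 and 1.17. Both were lowest on the PRA arrays of samples 1 and 2 (GAPDH 0.108 and 0.0444, ACTB 0.591 and 0.659), where the other arrays had ACTB values of 0.853 or more.

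PGR (chromosome 11, 101029624 to 101129813 in GRCh38), read by its only probe set with a single symbol, averaged 5.40 ± 0.20 (SD) in siCtrl and 5.13 ± 0.37 in siPGR. The signal with siPGR was 0.67 lower than with siCtrl in cell sample 1 and 0.13 higher in cell sample 2, at levels close to the filter, which lay between 5.40 and 5.45 on the arrays. Silencing was therefore not detectable in both cell samples with this probe set, and siPGR below means cells labelled as treated with that siRNA. PGR averaged 6.20 ± 0.16 with PRA, 7.91 ± 1.38 with PRB and 8.02 ± 0.37 with both isoforms. Both siPGR signals (4.87 and 5.39) lay below the filter value of their array, so the size of a rise over siPGR cannot be read from them. PGR signals were above siPGR in both cell samples with PRB and with PRA, and neither arm passed adjustment (limma adjusted p = 0.335 and 1.00). For any gene, no fold is given where the mean signal of a compared group lay below the filter, and a log2 value is then a difference between signals, not between amounts of RNA. Over the 4 arrays with PRB against the 4 siPGR and PRA arrays, PGR rose by 2.30 with the sample number as a block (SE 0.35, adjusted p = 0.0247; 0.0777 without the block). The position of the probes relative to the transgenes is not known.

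**Figure D1:**
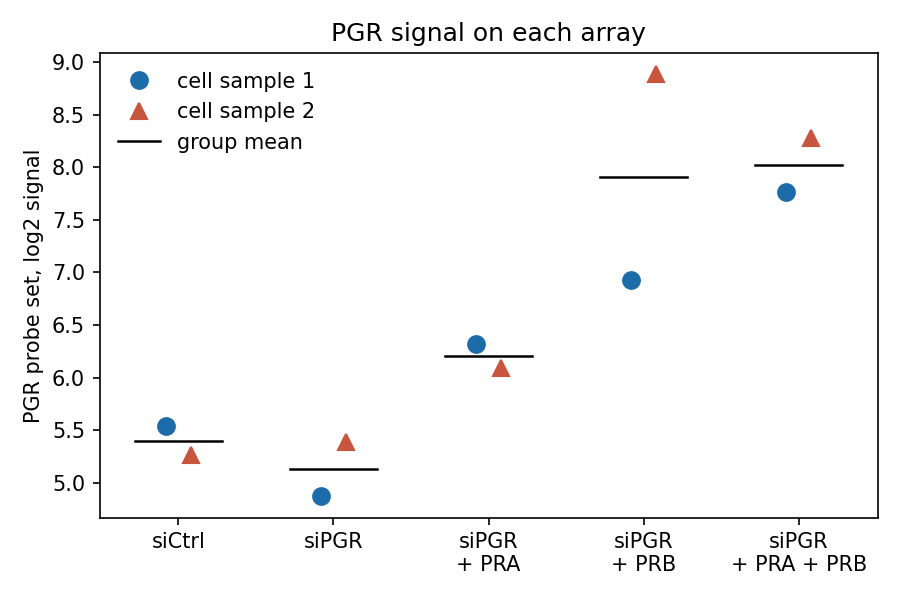
Log2 signal of the PGR probe set on each of the 10 arrays, by arm, with circles for cell sample 1, triangles for cell sample 2 and bars for the mean of the 2 arrays. Signals lay between 4.87 and 5.54 in the siCtrl and siPGR arms, at 6.32 and 6.09 with PRA, and between 6.93 and 8.88 in the arms with PRB.

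Cells labelled siPGR were compared with the control siRNA, a comparison designed to ask what endogenous PGR regulates, although PGR was not lower with siPGR in cell sample 2. Metallothioneins, small metal-binding proteins, were lower as a list with siPGR, with a median log2 difference of -0.54 and all 8 measured members lower in both cell samples. MT1M and MT1E differed by -0.82 (SE 0.62) and -0.46 (SE 0.16). Syndecan SDC1 was 3.09-fold lower (log2 -1.63, SE 0.43), SKP2, a subunit of a ubiquitin ligase, 2.15-fold lower (-1.10, SE 0.42) and FRAT2 1.89-fold lower (-0.92, SE 0.28), each in both cell samples. TGFBR3, a co-receptor of TGF-beta, was 1.71-fold higher (0.77, SE 0.24). With PRA, PRB or both returned, SDC1, SKP2 and FRAT2 were still below, and TGFBR3 above, siCtrl of the same cell sample. In cell samples 1 and 2 the FRAT2 signal was 6.96 and 6.57 with PRB, against 7.94 and 7.42 in siCtrl. None of these genes passed the test, nor did MEX3D (-1.33, and -0.06 on its other probe set), NDUFB2 (-0.86), NPY1R (0.92), GCA (0.74), MBP (0.76) or DLEU2 (0.57).

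Limma called 0 of 8243 genes for siPGR against siCtrl (lowest adjusted p = 0.173 with the block). An unadjusted p under 0.05 was reached by 100 (253 with the block), where chance gives 412. The SE is pooled over all arms, and its median without the block (0.18) exceeded the SD of the log2 differences (0.16). A count under 412 therefore does not show less change than chance. Camera called the metallothionein list alone (adjusted p = 8.41e-12), which had an adjusted p = 0.447 with an estimated correlation, and 0 of its members passed when adjusted over the list alone, 5 of 8 with the block. The block added the matrix protease list (median -0.12, adjusted p = 0.00135) and the progesterone and glucocorticoid responsive list (-0.08, 0.0486), at adjusted p = 0.511 with an estimated correlation for each. Fry called 0 of 27 lists. Camera called 6 lists without siCtrl of sample 2, and 2 without siCtrl of sample 1, siPGR of sample 1 or siPGR of sample 2.

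Return of PRA alone was compared with siPGR. No gene list was called: median differences of the 27 lists lay between -0.10 (endothelial markers) and 0.09 (the 1 measured leukocyte marker), and the lowest camera adjusted p was 0.581. With 2 arrays per arm, and recovery simulated for PRB alone, this does not show that PRA moved no gene. The G2 and M phase list differed by -0.05 in cell sample 1 and 0.01 in cell sample 2, and the interferon list by -0.10 and 0.03. The largest differences that both cell samples shared were small. TAF9B was 1.72-fold higher (log2 0.78, SE 0.29) and EGFR, the epidermal growth factor receptor, 1.38-fold (0.47, SE 0.26), and the signals of LIMD1 and ATP11A, below the filter in siPGR, were higher by 0.76 (SE 0.28) and 0.51 (SE 0.19). MRPL52 (-0.52), RPS6KA2 (-0.47), RADX (-0.46), GRP (-0.47) and IER3IP1 (-0.42) were lower, and none passed the test. The other probe sets of these genes, all dimmer, differed by less or in the opposite direction: -0.35 for LIMD1, 0.24 and 0.00 for TAF9B, -0.16 and -0.18 for ATP11A, between -0.11 and 0.15 for EGFR, -0.10 for RPS6KA2 and -0.03 for RADX. Against siPGR, PRA left 0 genes past limma's test, and fry called 0 lists. An unadjusted p under 0.05 was reached by 21 genes (83 with the block), against 412 by chance if the SE suited this comparison. The SD of the log2 differences over the genes was 0.12, under the median SE of 0.18 (0.13 with the block). The SE is pooled over all arms, so a count under 412 does not show less change than chance. Leaving out siPGR of cell sample 2 let camera call 3 lists, and leaving out siPGR of sample 1, PRA of sample 1 or PRA of sample 2 let it call 2, 1 and 1.

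Return of PRB alone was compared with siPGR. Genes of cell division were lower with PRB as lists. The G2 and M phase list had a median difference of -1.82 over 40 members, 38 of them lower in both cell samples, at -2.65 in sample 1 and -0.91 in sample 2. The S phase list had a median of -1.11 over 37 members, 25 of them lower in both, at -2.02 in sample 1 and -0.13 in sample 2. HELLS, a chromatin remodeller of dividing cells, was below the filter with PRB (signal difference -2.36, SE 0.22). DEPDC1 was 7.44-fold lower (log2 -2.90, SE 0.37), DLGAP5, a spindle protein, 4.57-fold lower (-2.19, SE 0.66, from -2.96 in sample 1 and -1.42 in sample 2), PARPBP 3.54-fold lower (-1.82, SE 0.41) and GINS4, a part of the replicative helicase, 2.81-fold lower (-1.49, SE 0.30). Histone genes were higher, with a median difference of 1.35 (0.72 in sample 1 and 1.92 in sample 2) and all 9 measured members higher in both cell samples, H2BC21 2.53-fold (1.34, SE 0.26). Interferon response genes had a median difference of 1.35, which came mostly from cell sample 2 (2.45), while the 0.24 of sample 1 was less than the 0.35 between siCtrl and siPGR of sample 2. The sign was positive in both cell samples for 26 of 34, with OASL 6.17-fold (2.63, SE 0.74, from 1.66 and 3.59), HERC5 5.24-fold (2.39, SE 0.75) and IFIT1 3.94-fold higher (1.98, SE 1.07). The PRB array of cell sample 2, where the interferon and histone lists were highest, also had the highest 3 prime minus 5 prime signals.

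Limma called 0 genes for PRB against siPGR, without or with the block, and the lowest adjusted p was that of HELLS (0.0798; 0.0672 with the block). Unadjusted p was under 0.05 for 820 genes (1605 with the block) against 412 by chance, and the difference exceeded a log2 value of 1 in both cell samples for 11 higher and 35 lower genes. Adjusted over the list alone, 28 of 40 G2 and M phase genes passed as lower (36 with the block), 0 of 37 S phase genes, 8 of 9 histone genes as higher, and 0 of 34 interferon genes (13 with the block). Camera called 11 lists. Those named had adjusted p = 1.18e-26 (G2 and M phase), 6.65e-15 (S phase), 8.58e-11 (histones) and 4.7e-07 (interferon). With an estimated correlation the same 4 had adjusted p = 0.323, 0.335, 0.221 and 0.379. Fry called 4 lists (histones, growth factors and inflammatory cytokines at 0.0255, cAMP responsive genes at 0.0278) and 7 with the block. With the block and without PRB of sample 1, 11 genes passed.

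The other called lists were higher with PRB. Metallothioneins had a median difference of 0.60 (adjusted p = 0.000149), matrix proteases 0.42 (0.000234), progesterone and glucocorticoid responsive genes 0.33 (0.00125), growth factors 0.22 (0.0117), inflammatory cytokines 0.26 (0.0120), extracellular matrix 0.12 (0.0309) and p53 targets 0.28 (0.0422). With an estimated correlation their adjusted p were 0.323, 0.301, 0.323, 0.221, 0.221, 0.323 and 0.608 in that order. Without the PRB array of cell sample 1, camera called 7 lists. The p53 targets were higher in cell sample 1 alone, with medians of 0.56 and -0.13, and without that array their median was -0.06.

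Lists that camera did not call for PRB against siPGR included the decidualization markers (median 0.24, adjusted p = 0.0920; 0.0461 with the block, 0.389 with the block and an estimated correlation). Medians were 0.31 for cAMP responsive genes, which fry called (0.0278), 0.28 for immediate early genes, 0.17 for TGF-beta signalling, 0.10 for the unfolded protein response, 0.09 for hypoxia and glycolysis and 0.09 for estrogen responsive genes. They were -0.09 for cholesterol synthesis, -0.08 for heat shock, -0.03 for Wnt signalling and -0.01 for steroid receptors. Among markers of cell types, medians were 0.27 for epithelial (8 genes), -0.03 for endothelial (5), 0.31 for leukocyte (1), -0.05 for smooth muscle (11) and 0.17 for stromal markers (17), and camera called none of them (adjusted p between 0.208 and 0.933).

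**Figure D2:**
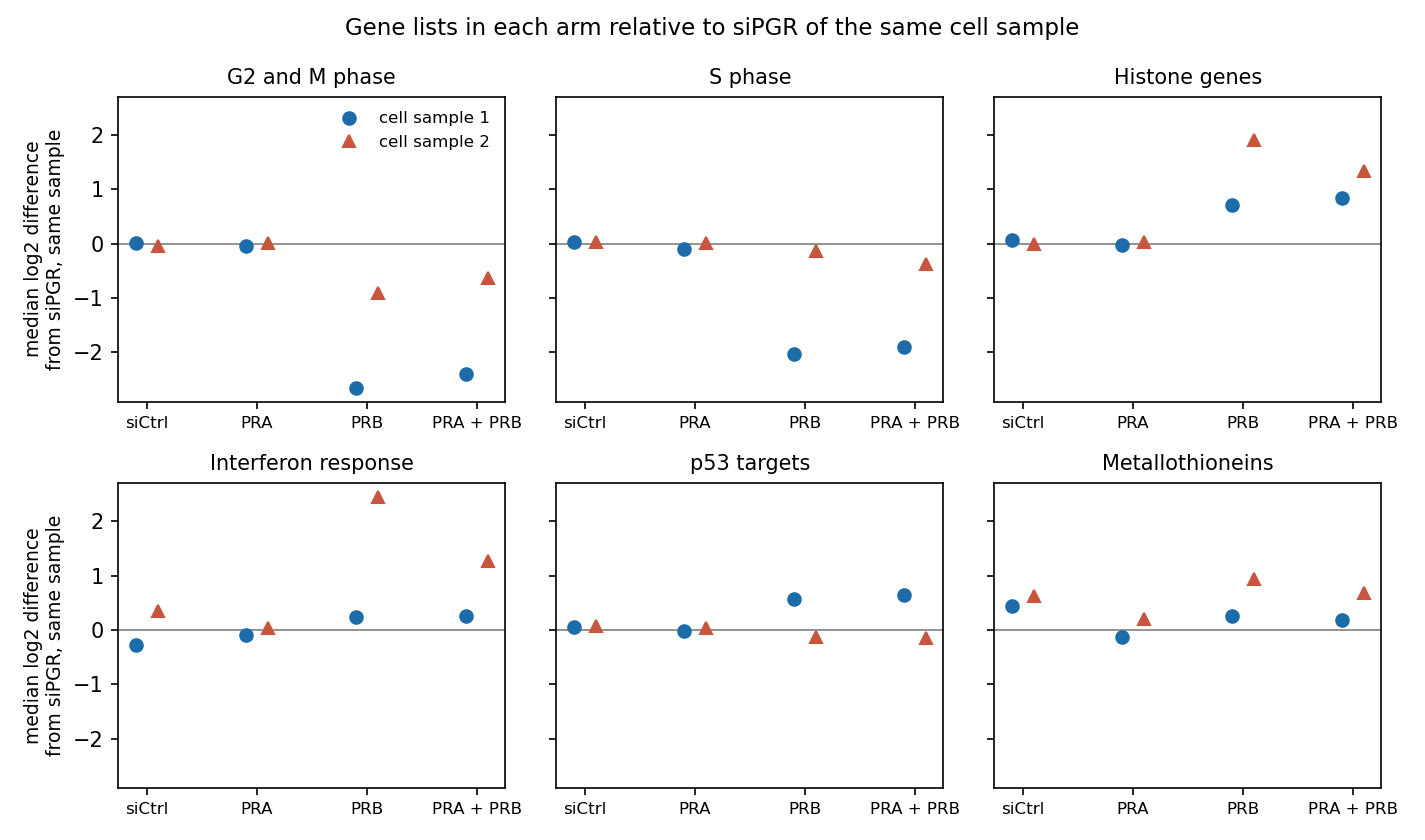
Median log2 difference of the members of 6 gene lists from siPGR of the same cell sample, for siCtrl and the 3 arms given virus, with circles for cell sample 1, triangles for cell sample 2 and the grey line at 0. With PRB the G2 and M phase list lay at -2.65 and -0.91 and the interferon list at 0.24 and 2.45, while with PRA both lists stayed between -0.10 and 0.03.

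Return of both isoforms was compared with siPGR. Both cell cycle lists were lower, G2 and M phase by a median of -1.52 (-2.40 and -0.63 in the cell samples) with 37 of 40 lower in both and S phase by -1.13 with 34 of 37 (-1.90 and -0.37 in the cell samples). Histone genes were higher by 1.22 (9 of 9, at 0.85 and 1.34) and metallothioneins by 0.46 (8 of 8, at 0.19 and 0.69). The interferon list had a median of 0.83, at 1.28 in cell sample 2 and at 0.26 in cell sample 1, again less than the 0.35 between siCtrl and siPGR, and 26 of 34 members were higher in both. HELLS was below the filter with both isoforms (signal difference -2.14, SE 0.22). DEPDC1 was 5.29-fold lower (log2 -2.40, SE 0.37), GINS4 2.99-fold (-1.58, SE 0.30), RPS6KA5 2.71-fold (-1.44, SE 0.39) and ZWILCH, a kinetochore protein, 2.39-fold lower (-1.26, SE 0.23). HERC5 was 3.25-fold higher (1.70, SE 0.75), OASL 3.07-fold (1.62, SE 0.74), the chemokine CXCL1 2.58-fold (1.37, SE 0.25) and IFIT1 2.56-fold (1.36, SE 1.07).

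Limma called 0 genes for both isoforms against siPGR, with 567 at an unadjusted p under 0.05 (1214 with the block) and a lowest adjusted p of 0.156 for HELLS (0.116 with the block). Adjusted over the list alone, 8 of 9 histone genes passed as higher and 0 of 40 G2 and M phase genes (29 lower with the block). Camera called 12 lists, the 11 called for PRB and the decidualization markers (median 0.21, adjusted p = 0.0423), and 0 with an estimated correlation (lowest adjusted p = 0.262). Fry called 0 lists, and 6 with the block: growth factors (0.00986), matrix proteases (0.0203), and progesterone and glucocorticoid responsive genes, inflammatory cytokines, TGF-beta signalling and histones (0.0411 each). Without the array with both isoforms of cell sample 2 camera called 5. The p53 targets (median 0.28, adjusted p = 0.0145) were at 0.65 and -0.15 in the cell samples, and at -0.11 without both isoforms of sample 1.

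PRB was compared with PRA to ask where the isoforms differ. Median differences were -1.80 for G2 and M phase genes (-2.62 and -0.96 in cell samples 1 and 2), -1.05 for S phase genes (-1.95 and -0.14), 1.35 for histone genes (0.77 and 1.94) and 1.38 for interferon genes (0.43 and 2.32). The HELLS signal, below the filter with PRB, was lower than with PRA (difference -2.12, SE 0.22). DEPDC1 was 6.18-fold lower (log2 -2.63, SE 0.37), CENPF 4.47-fold (-2.16, SE 0.55, from -2.92 and -1.40), KIF14 4.08-fold (-2.03, SE 0.68) and ZWILCH 3.02-fold (-1.60, SE 0.23). The RSAD2 signal, below the filter with PRA, was higher by 2.68 (SE 1.56, from 1.59 and 3.77), OASL was 4.85-fold higher (2.28, SE 0.74, from 1.33 and 3.23), HERC5 4.33-fold (2.12, SE 0.75), IFIT1 3.51-fold (1.81, SE 1.07) and the histone gene H2BC5 3.05-fold (1.61, SE 0.22). PGR itself was 3.26-fold higher with PRB than with PRA (1.70, SE 0.57, from 0.61 and 2.80), so the arms differed in PGR signal as well as in isoform. They also stood apart in the control signals, with the lowest 3 prime minus 5 prime values on both PRA arrays and the highest on the PRB array of sample 2.

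Limma called 0 genes between PRB and PRA, with 802 at an unadjusted p under 0.05 (1642 with the block) and a lowest adjusted p of 0.169 for HELLS (0.0580 with the block). Adjusted over the list alone, 21 of 40 G2 and M phase genes passed as lower (35 with the block) and 8 of 9 histone genes as higher. Camera called 9 lists, G2 and M phase at adjusted p = 1.94e-28 (adjusted p = 0.330 with an estimated correlation), and 0 with an estimated correlation. The block added extracellular matrix (median 0.16, adjusted p = 0.0188), cAMP responsive (0.30, 0.0303) and immediate early genes (0.32, 0.0303), at adjusted p = 0.502, 0.320 and 0.385 with an estimated correlation. Fry called 4, and 8 with the block. With the block and without PRB of sample 1, 12 genes passed.

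PRB added to PRA, read as both isoforms against PRA alone, gave medians of -1.51 for G2 and M phase (-2.38 and -0.65 in cell samples 1 and 2), -1.15 for S phase (-1.79 and -0.39), 1.24 for histone (0.86 and 1.36) and 0.88 for interferon genes (0.45 and 1.24). HELLS was below the filter with both isoforms (signal difference -1.89, SE 0.22) and CXCL1 was 2.47-fold higher (log2 1.30, SE 0.25). The PRA arrays compared here also had the lowest 3 prime minus 5 prime values. No gene passed limma's test (0), with 587 at an unadjusted p under 0.05 (1316 with the block). Camera called 10 lists, 5 without the array with both isoforms of cell sample 2, and 0 with an estimated correlation (lowest adjusted p = 0.312). The block added extracellular matrix (median 0.14, adjusted p = 0.0191), cAMP responsive (0.31, 0.0396), heat shock (-0.11, 0.0401) and decidualization genes (0.20, 0.0405), at adjusted p = 0.473, 0.332, 0.369 and 0.369 with an estimated correlation. Fry called 3, and 8 with the block, and the p53 targets (median 0.27) turned to -0.09 without both isoforms of sample 1.

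PRA added to PRB, read as both isoforms against PRB alone, gave small differences. RADX, PDE5A and SPARCL1 had mean signals below the filter in 1 or both arms, with signal differences of 0.62 (SE 0.27), 0.53 (SE 0.18) and -0.66 (SE 0.87), none past the test. The interferon list was lower by a median of -0.58, with -0.01 in cell sample 1 and -1.17 in cell sample 2 (camera adjusted p = 6.19e-07; adjusted p = 0.775 with an estimated correlation). The G2 and M phase list was higher by 0.28, with 0.24 and 0.30 (0.000332; 0.775 with an estimated correlation). By limma 0 genes passed, with 15 at an unadjusted p under 0.05 (60 with the block), and fry called 0 lists. Camera called 6 lists without PRB of sample 1 or both isoforms of sample 2, and 4 without both isoforms of sample 1 or PRB of sample 2, and with the block 1 gene passed without PRB of sample 1. The direction of both lists turned when single arrays were left out, with medians between -1.72 and 0.64 for interferon and between -0.53 and 1.11 for G2 and M phase. The interferon list turned without both isoforms of sample 1 (0.19) or PRB of sample 2 (0.64), and G2 and M phase without PRB of sample 1 (-0.50) or both isoforms of sample 2 (-0.53).

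The departure of both isoforms from the sum of the single-isoform changes was tested next. The RADX signal, below the filter in the 3 arms given virus, lay 1.08 above the sum (SE 0.39), and the interferon gene IFIT2 (-0.95, SE 0.50) below it, neither past the test. The interferon list lay below the sum by a median of -0.53, with 0.09 in cell sample 1 and -1.22 in cell sample 2 (camera adjusted p = 0.000261; adjusted p = 0.720 with an estimated correlation). It turned to 0.14 without both isoforms of sample 1 and to 0.77 without PRB of sample 2. The block added matrix proteases (median -0.11, adjusted p = 0.00246; 0.733 with an estimated correlation). Here limma called 0 genes, with 18 at an unadjusted p under 0.05 (63 with the block, where 1 gene passed without PRB of sample 1), and fry 0 lists. Camera called 0 lists without PRA of sample 2, 2 without siPGR of sample 2, 4 without PRA of sample 1 or PRB of sample 2, and 6 without PRB of sample 1 or either array with both isoforms.

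The 4 arrays with PRB were pooled against the 4 siPGR and PRA arrays, a comparison chosen after the data had been seen. The lowest and highest 3 prime minus 5 prime values stood on opposite sides of it. HELLS (chromosome 10, 94545788 to 94613905) fell to signals below the filter on all 4 arrays with PRB (signal difference -2.13, SE 0.15, adjusted p = 0.0150), by -2.09 in cell sample 1 and -2.16 in cell sample 2. It was the 1 gene that limma called without the block, where 1447 had an unadjusted p under 0.05. The call was lost (0 genes) without siPGR or PRA of either sample or PRB of sample 2, where the lowest adjusted p lay between 0.0889 and 0.138, and 2 genes passed without PRB of sample 1. With the sample number as a block, 687 genes passed, of which 429 rose and 258 fell. In the pooled fits the arrays with PRB alone and with both isoforms of a cell sample counted as separate replicates. Their deviations from the group mean correlated at 0.89 across genes. Calls and SE of the pooled comparisons therefore do not measure the spread of the PRB change between the cell samples. The calls and SE given for members of the lists are from that fit.

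Of the G2 and M phase genes 22 of 40 fell (38 adjusted over the list alone), with list medians of -2.54 in cell sample 1 and -0.79 in cell sample 2, among them CENPF 3.78-fold (log2 -1.92, SE 0.31), BIRC5, an inhibitor of apoptosis in mitosis, 3.38-fold (-1.76, SE 0.29), CCNB1, the mitotic cyclin, 3.14-fold (-1.65, SE 0.29) and AURKA 2.78-fold (-1.48, SE 0.24). DLGAP5, ASPM, KIF20A, HMMR, TTK, NEK2, CDC25C and PRC1 fell by log2 values between -1.96 and -1.76, and DEPDC1 by -2.52. Of the S phase genes 5 of 37 fell (28 adjusted over the list alone), with medians of -1.92 and -0.27, such as MCM4 (-1.15, SE 0.21), TYMS (-0.97, SE 0.16) and TK1 (-0.96, SE 0.17). Histone genes rose in 8 of 9 (9 adjusted over the list alone), with medians of 0.79 and 1.64, H2AC6 2.48-fold (1.31, SE 0.10) and H2BC5 2.67-fold (1.41, SE 0.13), with H4C8 (1.37) and H2BC12L (1.34). Interferon genes rose in 9 of 34 (24 adjusted over the list alone), with list medians of 0.36 in cell sample 1 and 1.80 in cell sample 2, such as RSAD2 (2.22, SE 0.43), OASL (1.95, SE 0.33), HERC5 (1.91, SE 0.27), ISG15 (1.58, SE 0.33), IFIT3 (1.43, SE 0.22) and IFIH1 (1.41, SE 0.32). The prostaglandin transporter SLCO2A1 rose by 1.60 (SE 0.36), mostly in cell sample 2 (2.41, against 0.80 in sample 1).

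Progesterone and glucocorticoid responsive genes rose in 7 of 26 (11 adjusted over the list alone), such as ANGPTL4 2.41-fold (log2 1.27, SE 0.14) and TSC22D3 (0.54, SE 0.07). Inflammatory genes rose in 5 of 23 (11 adjusted over the list alone), CXCL1 by 1.27 (SE 0.17) and PTGS2, a prostaglandin synthase, by 0.86 (SE 0.14). Matrix proteases rose in 8 of 20 (13 adjusted over the list alone), MMP10 by 1.00 (SE 0.17) and MMP14 by 0.50 (SE 0.09). Growth factors rose in 5 of 33 (7 adjusted over the list alone), such as EDN1 by 1.00 (SE 0.20, from 0.66 in cell sample 1 and 1.35 in cell sample 2), and metallothioneins in 2 of 8 (7 adjusted over the list alone), MT1M by 0.63 (SE 0.13) and MT1E by 0.51 (SE 0.10). Of the decidualization markers 3 of 23 rose and 1 fell. BMP2, a growth factor of decidualization, rose 1.84-fold (0.88, SE 0.13, adjusted p = 0.0236), HSD11B1, which activates cortisone, by 1.17 (SE 0.27, 0.0482) and the deiodinase DIO2 by 0.51 (0.0483), and the prostaglandin receptor PTGER2 fell by 0.48 (0.0217). The rise came mostly from cell sample 2 for HSD11B1 (0.58 in sample 1 and 1.77 in sample 2) and DIO2 (0.26 and 0.76). IGFBP1 (-0.34, SE 0.19), FOXO1 (0.15, SE 0.10), HAND2 (-0.02, SE 0.06), CEBPB (0.17, SE 0.07) and FOSL2 (0.40, SE 0.15) did not pass.

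Camera without the block called 11 lists for this pooled comparison, G2 and M phase (median -1.66) at adjusted p = 5e-28 (adjusted p = 0.316 with an estimated correlation), and 0 with an estimated correlation. The block added decidualization markers (median 0.20, adjusted p = 0.0339) and cAMP responsive genes (0.33, 0.0373), at adjusted p = 0.381 and 0.326 with an estimated correlation. Fry called 5, and 17 with the block, and camera 7 without PRB of sample 1. In exact permutation of the list scores 14 of 27 lists reached the smallest p that the 4 against 4 arrays allow (p = 0.0286), which came to 0.0551 after adjustment over the 27 lists, and the interferon list did not reach it (p = 0.171). Among the 14 were markers of cell types, higher with PRB by a list score of 0.20 (epithelial), 0.25 (the 1 leukocyte marker) and 0.12 (stromal). Permuted within the cell samples, 21 of 27 lists, interferon among them, reached the smallest p those splits allow (exact p = 0.0556). The count of 687 fell to 0 when any of the 4 siPGR or PRA arrays was left out, where the lowest adjusted p lay between 0.0585 and 0.0970. It was 1144 without PRB of sample 1, 2 without both isoforms of sample 1, 400 without PRB of sample 2 and 53 without both isoforms of sample 2, and all 687 kept their sign throughout.

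The 4 arrays with PRA, pooled against the 4 siPGR and PRB arrays in the same way, showed 0 called genes by limma with or without the block, and 13 and 56 at an unadjusted p under 0.05. TAF9B (log2 0.42, SE 0.20) and ATP11A (0.40, SE 0.14) were higher in both cell samples, but not on their other probe sets (0.03 and 0.06, and 0.00 and -0.12). Camera called the interferon list (median -0.22, adjusted p = 0.0135) and the G2 and M phase list (0.11, 0.0135), each at adjusted p = 0.982 with an estimated correlation. Both turned when single arrays were left out, interferon to 0.10 without both isoforms of sample 1 and 0.33 without PRB of sample 2, and G2 and M phase to -0.27 without PRB of sample 1 and -0.25 without both isoforms of sample 2. Fry called 0, and camera 1 list without PRA of sample 1 or siPGR of sample 2, 4 without both isoforms of sample 2, 5 without PRB of sample 2 and 6 without PRB of sample 1.

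The changes were also compared with each other across the 8243 genes, which are not independent replicates. The PRB change and the change with both isoforms correlated at r = 0.95, where unchanged arms sharing the siPGR arrays gave 0.50 in simulation, and at 0.31 and 0.28 when taken from different cell samples with no shared array. The PRA and PRB changes correlated at 0.22, against 0.50 simulated, and at -0.04 and 0.01 with no shared array. Between the cell samples the PRA change correlated with itself at 0.15 and the PRB change at 0.26, which limits what these values can show. The PRB change had the wider spread (SD of the log2 differences 0.39, against 0.12 for PRA), unlike the simulated arms. The 0.22 can therefore not be read as less sharing than in unchanged arms. The covariance was 0.0099, against 0.0068 simulated. The siPGR change from siCtrl correlated with the PRA, PRB and combined changes at -0.22, -0.24 and -0.19, against -0.50 simulated for each. The spreads differed here too (SD 0.16 for siPGR against siCtrl, 0.33 for both isoforms), with the same limit. The covariances were -0.0042, -0.0149 and -0.0103 in that order, against -0.0068 simulated for each. With no shared array the correlations were 0.02 and 0.00 for PRA, 0.09 and -0.06 for PRB, and 0.05 and -0.04 for both isoforms. The siPGR change itself correlated between the cell samples at only 0.03. Values near 0 therefore cannot decide whether the siPGR change was reversed across all genes. The metallothionein list, the 1 list camera called for siPGR without the block, had the opposite sign with PRB. The siPGR arrays enter both differences, and the list was picked for its low values on them. An opposite sign can therefore arise without a reversal. In cell samples 1 and 2 siCtrl lay above siPGR by 0.44 and 0.63, PRB by 0.26 and 0.94 and both isoforms by 0.19 and 0.69. With PRA this list differed from siPGR by -0.12 and 0.19.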

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

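All comparisons and tests of causes in this part were chosen after the data had been seen. The change with PRB (4 arrays with PRB against the 4 siPGR and PRA arrays) differed between the cell samples for 1666 of 8243 genes by limma's interaction term, with sample 1 above sample 2 for 657 and below for 1009. In this fit the arrays with and without PRA of the same cell sample stood in for replicates. Neither a cell sample nor an arm within it was replicated, so the count and the list tests that follow do not measure the spread between cell samples. The count was 640 without siPGR of sample 2, 775 without PRB of sample 1, 881 without both isoforms of sample 1, 945 without siPGR of sample 1, 953 without PRA of sample 1 and 986 without PRA of sample 2. A difference between the cell samples by camera was found for the 6 lists that follow, each lost with an estimated correlation (adjusted p = 0.0591 for p53 targets and between 0.479 and 0.817 for the others). List values are medians over the members of sample 1 minus sample 2.

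The first pattern was lower cell cycle genes in the arms with PRB. The fall was larger in cell sample 1, by -1.67 for G2 and M phase (camera adjusted p = 6.72e-28) and -1.60 for S phase (7.93e-23). Causes were tested on the G2 and M phase list alone. Its values argue against RNA integrity, since the 3 arrays with PRB, alone or with PRA, that had ordinary 3 prime minus 5 prime signals fell by 0.63 or more. The 0.63 was that of both isoforms in sample 2, where S phase fell by 0.37. Transduction as such is argued against by the 2 PRA arrays, which changed by a mean of -0.0212, at a virus dose that the labels do not give. For S phase the PRA arrays changed by -0.10 in sample 1 and 0.01 in sample 2, where siCtrl and siPGR differed by at most 0.03. The G2 and M phase values also argue against the amount of PGR RNA acting alike in both samples. Sample 1 had the lower PGR signal (7.34 against 8.58) and the larger fall (difference -1.76). An effect of PRB itself may account for the fall, but the dose of the PRB virus, or a property of it other than PRB, was not tested and stays open.

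The second pattern was higher interferon genes in the arms with PRB, larger in cell sample 2 (sample 1 minus sample 2 -1.30, camera adjusted p = 8.94e-06). Transduction as such is argued against by the PRA arrays, which changed by a mean of -0.0344, but only at the dose those arms received, which the labels do not give (PGR signal 6.20 with PRA, 7.91 with PRB). The amount of PGR RNA or of virus cannot be told apart from the cell sample: the 4 arrays with PRB ranked by interferon change as by PGR signal (1-sided exact permutation p = 0.0417, the smallest that 24 orders allow, reached by 3 of 5 lists, histones and S phase included) but not as by the PGR change from siPGR (p = 0.167). RNA integrity cannot be told apart. Of the 3 arrays with PRB that had ordinary control signals, only that with both isoforms of sample 2 clearly showed the rise (1.28). In sample 1 PRB and both isoforms changed by 0.24 and 0.26, less than the 0.35 between siCtrl and siPGR of sample 2. Evidence against RNA integrity as the cause thus rests on 1 array. An effect of the isoform PRB stays open too, since the arms with PRB had the higher PGR signal.

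The third pattern was the p53 targets, which moved apart between the cell samples (0.79, camera adjusted p = 5.64e-10), at 0.59 in sample 1 and -0.15 in sample 2. The quality of the PRB array of sample 2 is argued against as the whole cause, since the arms with both isoforms alone differed by 0.79. A difference between the cell samples in their response may underlie it, and the labels give nothing that would test this. The amount of PGR RNA or of virus cannot be told apart from the cell sample, since the mean PGR signal with PRB was 7.34 in sample 1 and 8.58 in sample 2.

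Metallothioneins also differed between the cell samples in their change with PRB (-0.47, adjusted p = 0.0465), as did histone genes (-0.45, 0.0356). Among 1501 probe sets with no single gene symbol, which the gene tests left out, 54 differed between the arms with and without PRB with the block (31 higher, 23 lower), 2 without it, and 0 between the arms with and without PRA.

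Other splits of the 8 arrays into 4 and 4 were refitted as plain pairs of groups, so counts differ from those of the 5-arm fit. Without the block the PRB split called 455 genes and 2 of 35 splits gave as many. The other of these, with 705 genes, parted cell sample 1 from cell sample 2, which points to a structure of the samples, and the remaining 33 splits called 0 genes by limma (at most 794 at an unadjusted p under 0.05). Chance was therefore not excluded over all 35 splits, and the 18 that keep the cell samples balanced, as the PRB split does, are too few for a share under 0.05. With the block the PRB split called 1733 genes and the highest other 0, with 1 of 18 splits as large, again too few. For lists, the PRB split called 11 without the block (highest other 11, 2 of 35 splits as large), where chance was not excluded, and 13 with it (highest other 13, 2 of 18 splits), where the splits are too few as well. The other splits called a median of 4 lists in each fit. The PRA split called 0 genes by limma (9 at an unadjusted p under 0.05, 34 with the block), a count that all 35 and all 18 splits reach by construction (highest other 705 and 1733), so the splits decide nothing about it.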

How the results depend on the processing

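The pooled comparisons, the interaction and the block joined to the trend and robust options were chosen after the data had been seen. Arrays carry no depth, and signals near the filter, such as PGR in the siCtrl and siPGR arms, limit what can be read. Without 1 array an arm holds 1, assumed to vary like the others, and without the block the arms then hold unequal cell samples. Unless stated, the cause of a change was not tested. Of 188 named values, 25 gained a call with the block, 30 with the block, trend and robust, 2 each with quantile normalization, trend and robust or the 60th percentile filter, and 0 with median centring, no filter, array weights or the mean of probe sets. HELLS lost its call with only the arms compared. Over all refits without 1 array, 57 values gained a call, 9 lost it (each HELLS) and 26 uncalled values changed sign by their SE or more. Quantile normalization moved no tested signal by more than 0.08 in log2.

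With the block, trend and robust, 11 genes passed for PRB against siPGR and 17 for PRB against PRA. Without 1 array in turn the counts ran from 0 to 11 and 0 to 12, and from 0 to 1 for both isoforms against PRB and for the departure from the sum. For the arms with PRB against those without (1 gene) the counts were 687 with the block, 8 with quantile normalization, 14 with the 60th percentile filter (fewer genes tested), 5 with trend and robust, 0 with only the arms compared (fewer arrays), 800 with the block, trend and robust, and 0 to 1144 without 1 array. The count of 687 became 344 with only the arms compared (325 shared), 259 with the 1.5-fold threshold and 0 to 1144 without 1 array. The interaction count (1666) ran from 640 to 2371.

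Every called list lost its call with an estimated correlation (0 in each comparison). Fry called 0 lists for siPGR, both isoforms against siPGR, both against PRB, the departure from the sum and the arms with PRA, 3 for both against PRA, 4 for PRB against siPGR and against PRA, and 5 for the arms with PRB. With the block fry called 6 for both against siPGR, 8 for both against PRA, 7 for PRB against siPGR, 8 for PRB against PRA, 17 for the arms with PRB and 0 for the others. Camera with the block called 3 for siPGR, 12 for PRB against siPGR, 12 for both against siPGR, 12 for PRB against PRA, 14 for both against PRA, 13 for the arms with PRB and 2 for the departure, and no filter 1 for the arms with PRA. Without 1 array camera called 2 to 6 lists (siPGR), 1 to 3 (PRA), 7 to 12 (PRB), 5 to 11 (both), 5 to 10 (both against PRA), 4 to 6 (both against PRB), 0 to 6 (departure), 7 to 12 (arms with PRB) and 1 to 6 (arms with PRA).

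The medians that turned without 1 array ran from -0.0628 to 0.57 (p53 targets, PRB), -0.11 to 0.67 (both) and -0.0944 to 0.68 (both against PRA). Interferon ran from -1.72 to 0.64 (both against PRB), -1.71 to 0.77 (departure) and -0.86 to 0.33 (arms with PRA), and G2 and M phase from -0.53 to 1.11 and -0.27 to 0.53 (both against PRB, arms with PRA).

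Correlations with no shared array (first effect from sample 1, then 2) were -0.0389 and 0.0132 for PRA with PRB, 0.31 and 0.28 for PRB with both, and, for siPGR against siCtrl, 0.0217 and 0.0022 with PRA, 0.0923 and -0.0564 with PRB, and 0.0528 and -0.042 with both. Over shared arrays with no filter, the correlations were -0.32 (siPGR against siCtrl with PRA), -0.23 (with both) and 0.91 (PRB with both). The offset was not run, the values being logs, nor were correlations over called genes, there being 0.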

Other observations

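The tests in this part were chosen after the data had been seen, and so were the genes named. Among genes whose change with PRB differed between the cell samples, the matrix protein gene DPT changed by 0.16 in sample 1 and 5.79 in sample 2, and the interferon gene MX1 by 0.90 and 3.74. CCNE2, a cyclin of the G1 to S transition, changed by -3.39 and -0.02, and the replication factor MCM10 by -3.34 and -0.11. GDF15, a stress-induced growth factor, changed by 1.99 and 0.35.

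A hypothesis was that histone transcripts rose in proportion to the fall of the cell cycle genes, as they might if both followed from 1 arrest. The sample with the larger cell cycle fall had the smaller histone rise, with a difference of -0.85 between the list medians of sample 1 and sample 2 over the arms with PRB (-0.45 as the median of the members' own differences), which argues against a proportion that holds across the cell samples.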
